A study of Mus musculus with 8 samples.

How the data were processed

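Total RNA of 2 mouse small intestinal organoid lines was extracted with an RNeasy kit, labelled with the Quick Amp two-colour kit and hybridised to Agilent whole mouse genome arrays, per the labels' protocols. Per the labels, Cy5 held the sample and Cy3 held control RNA of the same line, with no dye swap. Spot brightness was read with Agilent Feature Extraction 10.5.1.1, per the file headers, and the intensity values deposited for each spot are the median pixel brightness of the spot and of its local background in both dyes, on a linear scale and not background-subtracted. Per the file headers, the log10 ratio of each spot is the software's background-subtracted and dye-normalised Cy5 over Cy3, with linear and lowess steps. The other columns used are deposited flags of 0 or 1 per spot, set by the software for signal well above background, saturation and outliers. The authors' series table held log2 values for 19228 spots, which equalled the software's ratio turned to log2 within 5e-10, so its direction, Cy5 over Cy3, its scale and its lack of further centring were settled. Its column medians were 0.0039, 0.017, -0.028 and -0.0080 for control, CHIR99021, VPA and the combination in line 1, and 0.0057, 0.036, -0.024 and -0.0026 in line 2; 0 of its columns were unmatched. How the authors went from ratios to gene calls is not given in the sources used here.

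Each array held 45018 spots, of which 1639 were controls. The design fixed beforehand named mean signals; the files used here hold medians, which were used in their place. Background was corrected with limma's normexp method (offset 50), ratios were normalised by loess within each array with control spots at weight 0, and spots with outlier flags were left out, while none was saturated. Spots marked as outliers were also left out when the normexp model was fitted, a departure from the usual fit on all spots that was chosen after the data were examined and after the fit on all spots had called 0 genes for CHIR99021. On the CHIR99021 array of line 1, 34 spots had a local background marked as an outlier beside a bright speck, with a Cy3 background of up to 76947. Fitting on all spots there put the model's noise SD at 905 in Cy3 and 192 in Cy5, against 1.02 and 1.14 without the marked spots and 0.779 to 3.94 on the other arrays under either fit. The counts from the fit on all spots stand beside the results they change. Ratios of the spike-in RNAs are not used here.

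The files give accessions but no gene symbols, so probes were named by matching unversioned accessions to a RefSeq gene table of assembly GRCm38.p6, used for names only. The file headers name build mm9, so no coordinates are given. Of 41174 distinct probes, 27479 matched a symbol; the rest kept their accession. Spots of a probe were averaged and each gene was represented by its probe of highest mean brightness over the 8 arrays; where another probe of a gene named against control differed by over 1.5 times, its value is given. Genes were kept if well above background in Cy5 on both arrays of at least 1 group, and 75 were dropped because a marked spot left no value on an array. This left 19285 genes, 14003 with a symbol. Olfm4, Muc2, Ccnd1, Hdac1, Pla2g2a and several alpha-defensins had no matched probe and are not analysed here.

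The 4 groups were fitted together in limma (lmFit and eBayes) on the log2 ratios of the 8 arrays with no further covariate, which left 4 residual degrees of freedom and 2.68 prior ones. The comparisons were each treatment with control, the combination with each single compound, and the interaction, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The replicate number is the organoid line, per the labels, and each slide held 1 line and all 4 groups, so line and slide coincide. Samples of a line deviated together from their group means, with r across genes from 0.122 to 0.755 for the 6 pairs of groups, and the fit with the line as a replicate block was an alternative. Within a line there is no residual degree of freedom, so line values are given without a test.

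The comparisons, tests, named genes, 28 gene lists and all alternatives but the normexp fit on all spots were fixed before the data were examined, unlike the handling of outlier spots in the main results. Named genes were 16 fixed markers, the 8 largest rises and 8 largest falls past the threshold that moved the same way in both lines (5 and 5 for the contrasts between treatments), leaving out names that are accessions, clone names or predicted loci, and up to 4 members of each list with the smallest adjusted p; some were left out of the text. Lists were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 28 lists and 6 contrasts (168 tests), with an estimated correlation and fry as alternatives. Lists covered stem cell, Wnt target, Paneth, goblet, enteroendocrine, tuft, enterocyte, M cell, fetal-like, Notch, secretory progenitor, G2/M, G1/S, cyclin-dependent kinase inhibitor and p53, histone deacetylase, replication-independent histone, neuronal, cholesterol synthesis, fatty acid oxidation and PPAR target, glycolysis, unfolded protein response, NRF2 and xenobiotic, interferon, MHC class II, antimicrobial, mesenchymal, leukocyte and endothelial genes.

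The other settings were Agilent's own log ratio, a normexp offset of 16, no background correction, median centring, scale normalisation between arrays, no filter or a filter on all 8 arrays, the mean of all probes, eBayes with trend and robust options, a minimum log2 fold change of 1, the replicate block, a fit of the compared groups alone, treated ratios against 0, the Cy5 channel alone with the block, the authors' table, each array left out in turn and the usual normexp fit on all spots, listed as an alternative once the fit without outlier spots had taken its place. The fit was tested on simulated data with 50 genes changed at each of 4 sizes. The simulated noise was independent between arrays, equal in all groups and without an effect of the organoid line, unlike the data. For CHIR99021 vs control it recovered 4% at a log2 change of 0.5, 84% at 1, 94% at 2 and 100% at 4, with 7 false calls among 19285 genes. For VPA vs control the shares were 6%, 82%, 94% and 98% with 12 false calls, and for the combination 8%, 88%, 98% and 100% with 5. R 4.3.3, limma 3.58.1, jsonlite 2.0.0 and the package data.table (version 1.17.8) were used.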

Results

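Messenger RNA was profiled in mouse small intestinal organoids, which are self-organising epithelial cultures that hold crypt stem cells and their absorptive and secretory progeny. Organoids were kept for 6 days in control medium, with 3 µM CHIR99021, with 1 mM valproic acid (VPA), or with both compounds at the same doses. CHIR99021 inhibits the kinase GSK3 and so stabilises beta-catenin, and VPA is a branched short-chain fatty acid that inhibits histone deacetylases. Each condition was measured in 2 independently established wild-type organoid lines, which gives 8 two-colour arrays, with 2 arrays per condition. The Cy5 channel held the sample and the Cy3 channel held control RNA of the same line, so each control array set control RNA against control RNA. The study's title names purified cultures of Lgr5-positive stem cells and their progeny, and the comparisons ask which stem, secretory and absorptive genes each compound and their combination moved.

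Between 60.6% and 64.6% of the spots of an array were well above background in Cy5, and 0 spots were saturated. The SD of the log2 ratios across genes was 0.23 and 0.20 on the control arrays of lines 1 and 2, where 44 and 19 genes lay over 2-fold either way. It was 0.42 and 0.38 with CHIR99021, 0.56 and 0.49 with VPA, and 0.68 and 0.54 with the combination, where 1886 and 1241 genes lay over 2-fold. The same control RNA, read in Cy3 on the 4 arrays of a slide, varied with a median SD of 0.065 (log2). The median SD between the 2 lines was 0.054 for control ratios, 0.0945 with CHIR99021, 0.125 with VPA and 0.127 with the combination. These values come from 2 ratios each and the Cy3 value from 4 readings of 1 dye, so their sizes cannot be compared directly. The control ratios of the 2 lines correlated across genes (r = 0.82; genes are not independent replicates), so the dyes had a repeatable bias, and every fold change against control below is the treated ratio minus the control ratio. Fold changes are log2 values ± SE with n = 2 arrays per group, and adjusted p-values are those of limma's moderated test over the 19285 genes tested. The number of arrays limits the precision: with 2 lines, p-values measure the spread between these lines only. Each control array held control RNA of its line in both dyes, so the control spread leaves out differences between control cultures. The fit pooled this spread with that of the treated arrays into 1 variance per gene. Contrasts between treated groups use no control array, yet their SE drew on the smaller control spread as well. With only the compared groups fitted, the combination against VPA called 0 genes in place of 215, and against CHIR99021 289 in place of 1928. That fit also leaves fewer residual degrees of freedom, so these cannot be told apart.

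With CHIR99021, genes of the absorptive enterocyte were lower as a list (adjusted p = 0.20 with an estimated correlation). The neutral amino acid transporter Slc6a19 fell by 2.76 ± 0.25 (adjusted p = 0.0142), the brush border enzymes Enpep and Treh fell by 2.39 ± 0.24 and 1.75 ± 0.13, and Dgat1, which makes triglycerides, fell by 1.28 ± 0.11. Among the 47 tested members of the enterocyte list, 0 rose, 9 fell and 38 did not pass. When adjusted over the list alone, 1 rose and 32 fell, and 44 had negative values (median -1.0; -0.95 in line 1 and -1.18 in line 2). Krt20 and Alpi, markers of differentiated enterocytes, had values of -1.98 ± 0.40 (adjusted p = 0.0914) and -1.58 ± 0.34 (adjusted p = 0.109), and both passed with the organoid line as a replicate block (adjusted p = 0.025 and 0.0148). A second Alpi probe read -0.49. The largest falls included Adh4 (-3.60 ± 0.38, adjusted p = 0.0179) and Adh1 (-2.78 ± 0.37), alcohol dehydrogenases that also act on retinol, and Arg2 (-2.82 ± 0.28), a mitochondrial arginase. Scin, an actin-severing protein, fell by 3.19 ± 0.34.

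Goblet, tuft, antimicrobial, fatty acid oxidation and NRF2 genes were lower as lists with CHIR99021 (adjusted p from 0.226 to 0.665 with an estimated correlation). Of 25 goblet cell genes, 3 fell (10 adjusted over the list alone) and 0 rose; they included the tissue kallikrein Klk1 (-2.02 ± 0.32) and the endoplasmic reticulum stress sensor Ern2 (-0.67 ± 0.10, adjusted p = 0.0436). None of the 24 tuft cell genes passed by limma, and 0 passed adjusted over the list alone, yet 23 had negative values (median -0.50). Among 13 antimicrobial and inflammation genes, 2 fell (3 adjusted over the list alone), the lectins Reg3g (-3.02 ± 0.38) and Reg3a (-2.83 ± 0.36). These lectins belong to a multigene family whose probes may cross-hybridise. The list's median was only -0.10, so its call rested on a part of its members. Of 32 genes of fatty acid oxidation and PPAR targets, 4 fell (10 adjusted over the list alone), among them the lipid transcription factor Creb3l3 (-2.07 ± 0.24) and the nuclear receptor Ppara (-0.89 ± 0.12). Of 29 NRF2 and xenobiotic genes, 1 fell (3 adjusted over the list alone), the retinal dehydrogenase Aldh1a1 (-2.49 ± 0.32). Cdkn2b, an inhibitor of G1 cyclin-dependent kinases, fell by 1.33 ± 0.11 (adjusted p = 0.0135).

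Genes of proliferation, stem cells and Wnt signalling were higher as lists with CHIR99021 by camera's test with a preset correlation, but not with an estimated correlation (adjusted p from 0.478 to 0.707). All 29 G2/M genes and 30 of 31 G1/S genes had positive values (medians 0.29 and 0.26), with 0 passing over all genes by limma and 0 adjusted over the list alone. The 29 stem cell genes had a median of 0.37 with 0 passing (1 rose adjusted over the list alone). Lgr5, the R-spondin receptor that marks crypt stem cells, read 0.90 ± 0.35 (adjusted p = 0.344; 0.92 and 0.87 in the lines). Of 26 Wnt targets, 1 rose (3 adjusted over the list alone): Nkd1, a feedback inhibitor of the pathway, at 1.18 ± 0.14 (adjusted p = 0.0254), although a second Nkd1 probe read 0.23. Axin2, another feedback inhibitor, read 0.69 ± 0.17 (adjusted p = 0.150). Of 11 genes of fetal-like and regenerative epithelium, 1 rose (4 adjusted over the list alone), the surface protein Ly6d (1.5 ± 0.17, adjusted p = 0.0235). Crip2, a LIM domain protein, rose by 1.04 ± 0.09, and the actin crosslinker Flna rose by 1.13 ± 0.15, with a further Flna probe at 0.00 and no call for the mean of its probes. Lyz1, the lysozyme of Paneth cells, read 0.88 ± 0.33 (adjusted p = 0.334).

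Over all genes, 22 rose and 194 fell with CHIR99021, and 2474 (1022 higher, 1452 lower) had an unadjusted p under 0.05. All calls had the same direction in both lines, here and in the comparisons below. This agreement is no separate support, since a gene whose lines differ in sign has too wide a spread to pass. Rises made up 10.2% of the calls, 23.7% (257 rose, 829 fell) with only the compared groups fitted and 55.1% (2381 rose, 1940 fell) when treated ratios were tested against 0. In camera's test of the lists against all other genes, those with lower values were enterocyte (adjusted p = 4.18e-21), fatty acid oxidation (4.08e-10), goblet cell (1.35e-07), tuft cell (0.000181), NRF2 (0.000505) and antimicrobial genes (0.00816). With an estimated correlation the adjusted p-values were 0.20, 0.473, 0.226, 0.665, 0.573 and 0.478. Those with higher values were G2/M (9.02e-08), G1/S (1.24e-06), stem cell (3.26e-06), fetal-like (2.22e-05) and Wnt target genes (0.000609). With an estimated correlation the adjusted p-values were 0.665, 0.707, 0.483, 0.298 and 0.478. By fry, enterocyte and goblet cell genes passed (adjusted p = 0.0141 and 0.0422), and the other lists called here did not (0.0656 to 0.308). The CHIR99021 count depended on whether outlier spots, among them those beside a bright speck on the array of line 1, entered the background model. That choice was settled after the data were examined, and the speck's spots alone were not tested. With outlier spots of all arrays kept in that model, 0 genes passed by limma (1564 with an unadjusted p under 0.05). None of the 20 called genes named here passed. The count was 557 (78 rose, 479 fell) with the line as a replicate block. It was 1 without control line 1, 1 without control line 2, 15 without CHIR99021 line 1 and 1 without CHIR99021 line 2. Each of these ended at least 19 of the 20 named calls. Leaving out VPA line 1 or line 2 ended that of Ern2 and let Lyz1 pass, and leaving out combination line 1 or line 2 ended it and let Krt20 pass. Agilent's own log ratios gave 36 genes and ended 15 named calls, leaving Arg2, Enpep, Dgat1, Cdkn2b and Crip2, and a variance trend with robust fitting gave 85 and ended 9, among them Adh4, Arg2, Dgat1, Crip2 and Nkd1. Ern2 and Klk1 lost their calls under several further settings. The NRF2 call ended without CHIR99021 line 2 (adjusted p = 0.0607), and the antimicrobial call ended when treated ratios were tested against 0 (adjusted p = 0.0798) and with no filter on dim probes (adjusted p = 0.0538).

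With VPA, genes of fatty acid oxidation were higher as a list (adjusted p = 0.396 with an estimated correlation). Of the 32 tested, 17 rose, 1 fell and 14 did not pass. When adjusted over the list alone, 24 rose and 1 fell, and 30 had positive values (median 0.91; 0.80 in line 1 and 1.1 in line 2). Cyp4a10, a fatty acid hydroxylase, rose by 4.90 ± 0.92 (adjusted p = 0.0235; other probes 3.24 and 2.03), the acyl-CoA thioesterase Acot1 by 3.16 ± 0.26 (adjusted p = 0.00209), and the mitochondrial enzymes Acaa2 and Cpt2 by 0.98 ± 0.11 and 0.93 ± 0.11. Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 3.64 ± 0.78, with 2.26 in line 1 and 5.02 in line 2, and the peroxisomal carnitine transferase Crot rose by 1.24 ± 0.11. Outside the list, the lipid droplet protein Cidea rose by 4.45 ± 0.68, the glucokinase regulator Gckr by 3.59 ± 0.38, Reg3g by 3.31 ± 0.38 and Crip2 by 3.22 ± 0.09 (adjusted p = 9.39e-05).

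Secretory lineage genes were lower as lists with VPA (adjusted p from 0.226 to 0.737 with an estimated correlation). Of 25 goblet cell genes, 11 fell and 0 rose (15 fell and 1 rose adjusted over the list alone), with a median of -1.21. Among them, the secreted goblet cell protein Clca1 fell by 3.11 ± 0.64 (-4.18 and -2.04 in the lines), the chemokine Ccl6 by 2.91 ± 0.53, the endosomal protein Rep15 by 2.74 ± 0.33, and Spdef, a transcription factor of goblet and Paneth cell maturation, by 1.58 ± 0.20. Of 27 enteroendocrine genes, 7 fell (8 adjusted over the list alone), with the granule protein Chgb at -3.08 ± 0.36 (adjusted p = 0.00549) and Tph1, the enzyme of serotonin synthesis, at -2.0 ± 0.25; a second Tph1 probe read -0.54 and the call ended with the mean of the probes. Ghrl, which encodes ghrelin, fell by 2.15 ± 0.42. Chga, another granule protein, read -2.51 ± 0.89 (adjusted p = 0.133; 0.0130 with the replicate block). Of 22 Paneth cell genes, 6 fell and 1 rose (8 and 1 adjusted over the list alone), including the alpha-defensin Defa22 (-1.34 ± 0.16), whose family members may cross-hybridise. Of 24 tuft cell genes, 1 fell, Lrmp (-1.38 ± 0.15), and 1 rose, with the same counts adjusted over the list alone; the list's median was -1.16 in line 1 and -0.23 in line 2. Of 12 secretory progenitor genes, 3 fell (3 adjusted over the list alone), among them the Notch ligand Dll1 (-0.81 ± 0.19, adjusted p = 0.0429).

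Cell cycle genes were lower and NRF2 genes higher as lists with VPA (adjusted p from 0.657 to 0.805 with an estimated correlation), and the enterocyte and stem cell lists did not pass. Of 31 G1/S genes, 3 fell (8 adjusted over the list alone; median -0.35), with thymidine kinase Tk1 at -0.96 ± 0.12. Of 29 G2/M genes, 2 fell (0 adjusted over the list alone; median -0.26), including cyclin B1, Ccnb1 (-0.56 ± 0.12, adjusted p = 0.0346; other probes -0.10 and -0.25). Of 29 NRF2 and xenobiotic genes, 3 rose (4 adjusted over the list alone; median 0.50), among them the metallothionein Mt1 (0.79 ± 0.11) and the glutathione transferase Gstm1 (0.96 ± 0.23, adjusted p = 0.0449; second probe 0.52). The calls of Ccnb1 and Gstm1 ended with the mean of their probes. Of 47 enterocyte genes, 5 rose and 4 fell (10 and 9 adjusted over the list alone; median -0.18, adjusted p = 0.749). The purine enzyme Ada rose by 0.97 ± 0.13 and the lipoprotein assembly factor Mttp by 0.64 ± 0.10, while apolipoprotein Apoa1 fell by 1.87 ± 0.31 and Treh by 0.95 ± 0.13. Fabp1, an intestinal and liver fatty acid binding protein, read 2.16 ± 0.60 (adjusted p = 0.0711). Of 29 stem cell genes, 2 fell and 0 rose (3 and 2 adjusted over the list alone; median 0.07, adjusted p = 0.981). The list member Gkn3, a gastrokine, fell by 2.20 ± 0.11, and Lgr5 read -0.26 ± 0.35 (adjusted p = 0.705) and 0.12 without VPA line 2. Of 26 Wnt targets, 2 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.0946, and 0.0116 without VPA line 2), with Nkd1 at 1.00 ± 0.14 and its second probe at -0.04.

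Single members of other lists passed as well. The linker histone gene H1f0 rose by 0.92 ± 0.12, the microtubule protein Mapt by 1.94 ± 0.09 (adjusted p = 0.000367) and the receptor Notch3 by 1.86 ± 0.18. The Notch target Hes1 fell by 0.66 ± 0.13, the deacetylases Hdac7 and Sirt1 by 0.93 ± 0.18 and 0.92 ± 0.14, and the lysosomal protease Ctss by 2.90 ± 0.19. The calls of Sirt1 and Mttp ended when treated ratios were tested against 0 (-0.29, adjusted p = 0.0615, and 0.17, adjusted p = 0.114).

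Over all genes, 1265 rose and 824 fell with VPA, so 60.6% of the calls were rises; the share was 76.7% with median centring in place of loess and 50% in the Cy5 channel alone. All calls had the same direction in both lines, which passing the threshold required. Camera gave adjusted p = 1.6e-12 for fatty acid oxidation, 1.56e-09 for goblet cell, 2.17e-05 for G1/S, 3.49e-05 for enteroendocrine, 0.000102 for G2/M, 0.00136 for Paneth cell, 0.00369 for tuft cell, 0.00754 for secretory progenitor and 0.00891 for NRF2 genes. Adjusted p-values with an estimated correlation were 0.396, 0.226, 0.737, 0.525, 0.805, 0.588, 0.737, 0.588 and 0.657. The count of 2089 was 3752 (2098 rose, 1654 fell) with the replicate block, 120 and 127 without control line 1 and control line 2, which ended 32 and 31 of the named calls, 1233 without CHIR99021 line 1 or line 2, 1145 without VPA line 1 and 1051 without VPA line 2. The last 4 each ended 7 or 8 named calls, Cyp4a10, Dll1 and Hes1 each time; the Cyp4a10 call also ended without either control array. Leaving out combination line 1 or line 2 let Fabp1 pass. Agilent's own log ratios ended the calls of Angptl4, Ccnb1, Clca1, Dll1, Gstm1, Hes1 and Notch3. A variance trend with robust fitting ended those of Apoa1, Ccl6, Clca1 and Dll1, and median centring (1130 genes) those of Ccnb1, Dll1, Hes1 and Mttp. The calls of Ccnb1, Mttp, Nkd1 and Treh ended with outlier spots of all arrays kept in the background model. The tuft cell call ended without VPA line 1 (adjusted p = 0.260), those of secretory progenitor and G2/M genes without VPA line 2 (adjusted p = 0.177 and 0.0614), and that of NRF2 genes when treated ratios were tested against 0 (adjusted p = 0.129).

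**Figure D1:**
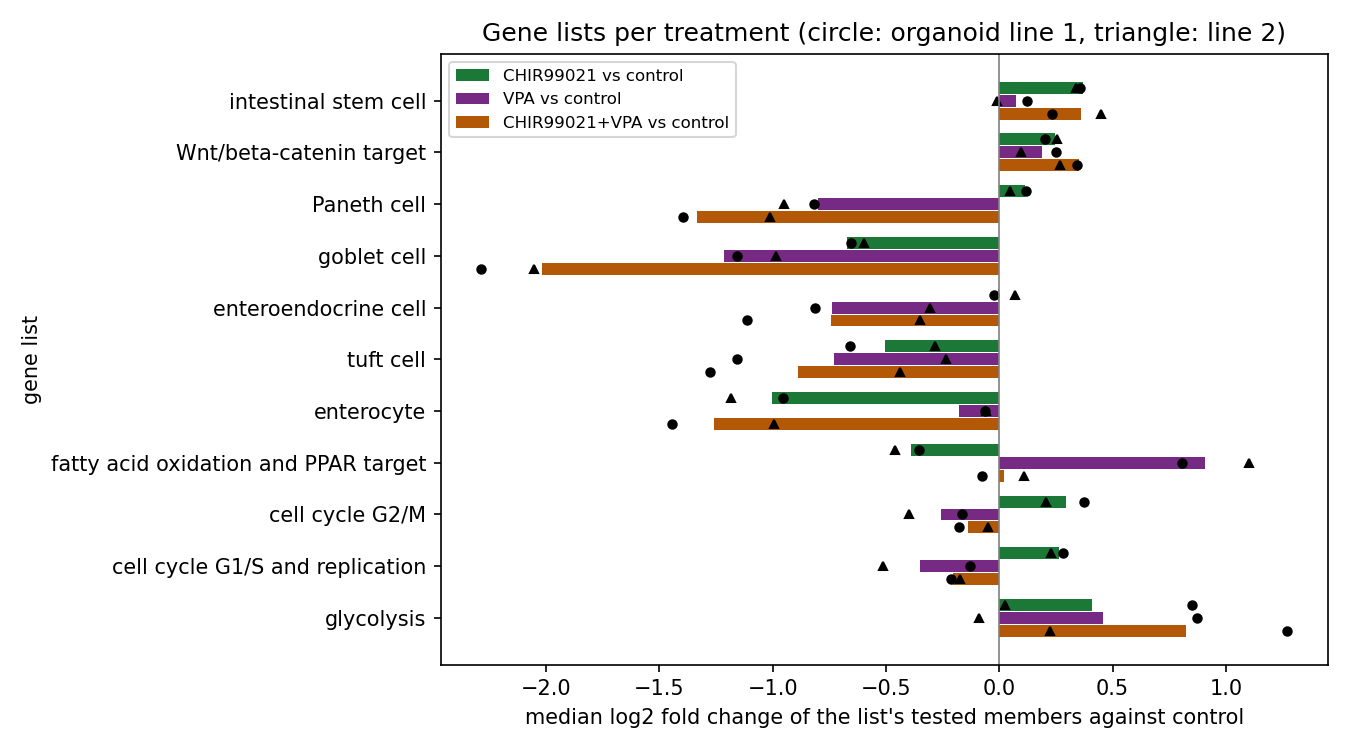
Median log2 fold change against control (horizontal axis) of the tested members of 11 gene lists (vertical axis) for each treatment, as bars, with the medians in organoid line 1 (circles) and line 2 (triangles). The enterocyte median was -1.0 with CHIR99021, -0.18 with VPA and -1.26 with both, whereas the fatty acid oxidation median was -0.39, 0.91 and 0.02.

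With CHIR99021 and VPA together, goblet, Paneth, enteroendocrine and enterocyte genes were lower as lists (adjusted p from 0.226 to 0.573 with an estimated correlation). Clca1 fell by 5.77 ± 0.64 (adjusted p = 0.00300), Chgb by 4.45 ± 0.36 (adjusted p = 0.00124), the alpha-defensin Defa23 by 4.05 ± 0.40 and Slc6a19 by 3.70 ± 0.25. Of 25 goblet cell genes, 16 fell and 1 rose (19 and 1 adjusted over the list alone; median -2.02), with Ccl6 at -4.91 ± 0.53, the mucus lectin Zg16 at -3.96 ± 0.82, Spdef at -2.65 ± 0.20 and the trefoil factor Tff3 at -1.97 ± 0.15. Of 47 enterocyte genes, 23 fell and 2 rose (30 and 2 adjusted over the list alone; median -1.26), with Apoa1 at -3.79 ± 0.31 and Alpi at -1.68 ± 0.34 (adjusted p = 0.0215). The second Alpi probe read -0.29 and the call ended with the mean of both. Cubn, an endocytic receptor for vitamin carriers, went the other way at 2.97 ± 0.21. Of 22 Paneth cell genes, 8 fell and 1 rose (12 and 2 adjusted over the list alone; median -1.33), among them the pentraxin Mptx1 (-5.33 ± 0.84) and the lectin Reg4 (-2.93 ± 0.24), while Lyz1 read -1.24 ± 0.33 (adjusted p = 0.0502; 0.0293 with the replicate block). Of 27 enteroendocrine genes, 6 fell (7 adjusted over the list alone; median -0.74). Of 24 tuft cell genes, 3 fell and 1 rose (6 and 1 adjusted over the list alone), with the taste channel Trpm5 at -1.63 ± 0.39. Of 12 secretory progenitor genes, 4 fell (6 adjusted over the list alone), including Dll1 (-1.09 ± 0.19) and Gfi1 (-1.54 ± 0.22), a transcription factor of secretory cells. Adh4 fell by 5.01 ± 0.38.

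Stem cell and Wnt genes moved both ways with the combination. Of 26 Wnt targets, 6 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.35). The receptor Tnfrsf19 rose by 3.66 ± 0.54, Nkd1 by 1.46 ± 0.14 (second probe 0.24), the transcription factor Tcf7 by 1.12 ± 0.14 and the ubiquitin ligase Rnf43 by 0.85 ± 0.13. The stem cell list overlaps with the Wnt list: Tnfrsf19, Rnf43, Lgr5, Ascl2, Sox9, Znrf3, Ephb2, Ephb3, Cd44 and Sp5 were fixed as members of both. Of 29 stem cell genes, 7 rose and 2 fell (9 and 3 adjusted over the list alone), with a median of 0.36. The falls were Gkn3 (-2.48 ± 0.11) and the zinc finger gene Zbtb38 (-0.94 ± 0.16). Camera gave adjusted p = 0.0564 for this list, 0.0357 with the replicate block and 0.864 with an estimated correlation. Camera's adjusted p was also 0.0454 with Agilent's own log ratios, 0.0089 with no filter and 0.0441 with outlier spots of all arrays kept. The list also passed without combination line 1 (median 0.43) and without any 1 of the CHIR99021 or VPA arrays (median 0.36). Lgr5 read 0.58 ± 0.35 (adjusted p = 0.329), with 0.01 in line 1 and 1.14 in line 2. Of 20 glycolysis genes, 2 rose and 1 fell, with the same counts adjusted over the list alone. The enolase Eno2 rose by 1.25 ± 0.21 and the phosphofructokinase Pfkm by 0.86 ± 0.18, and the list's median was 1.27 in line 1 and 0.22 in line 2. Of 31 G1/S genes, 1 rose and 2 fell (0 and 2 adjusted over the list alone; median -0.20), with Tk1 at -0.87 ± 0.12. Of 29 G2/M genes, 0 passed by limma and 0 adjusted over the list alone (median -0.14). Of 32 fatty acid oxidation genes, 4 rose and 4 fell (8 and 4 adjusted over the list alone; median 0.02, adjusted p = 0.977). Outside these lists, Cidea rose by 4.76 ± 0.68, the secreted lectin Lgals1 by 4.19 ± 0.55, the signalling regulator Rgs10 by 3.40 ± 0.10 and Crip2 by 3.14 ± 0.09 (adjusted p = 7.49e-05 for the last 2). As with VPA alone, H1f0 (1.12 ± 0.12), Notch3 (2.19 ± 0.18) and Mapt (1.89 ± 0.09) rose and Hes1 (-0.67 ± 0.13) fell.

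Over all genes, 1620 rose and 1367 fell with the combination, all in the same direction in both lines, as passing required. Rises made up 54.2% of the calls, and 65.2% with median centring. Camera gave adjusted p = 3.78e-13 for goblet cell, 2.7e-10 for enterocyte, 2.07e-05 for Paneth cell, 0.00016 for enteroendocrine, 0.000332 for tuft cell, 0.00644 for secretory progenitor, 0.0121 for Wnt target, 0.0196 for glycolysis, 0.0361 for G1/S and 0.0486 for G2/M genes. Adjusted p-values with an estimated correlation were 0.226, 0.226, 0.483, 0.573, 0.665, 0.588, 0.588, 0.926, 0.926 and 0.927. The count of 2987 was 4822 (2557 rose, 2265 fell) with the replicate block, 542 and 602 without control line 1 and control line 2, which ended 16 and 14 named calls, and 1784 without combination line 1, which ended 4. The calls of Alpi and Zg16 ended without combination line 2 and that of Trpm5 without CHIR99021 line 1 or line 2, while Lyz1 passed without VPA line 1 or line 2. Median centring ended the calls of Dll1 and Hes1, and Agilent's own log ratios that of Eno2. That of Alpi ended with outlier spots of all arrays kept in the background model. The G2/M call ended with the replicate block (adjusted p = 0.0573) and without control line 1 (0.0576), control line 2 (0.0798), CHIR99021 line 1 (0.0528) or combination line 1 (0.345). The call of G1/S genes ended without control line 2 (0.0608), combination line 1 (0.0574) or combination line 2 (0.0788), and that of glycolysis ended without combination line 1 (median 0.19, adjusted p = 0.583). When treated ratios were tested against 0, the Wnt and glycolysis calls ended (adjusted p = 0.0690 and 0.0563), and Agilent's own log ratios ended those of G2/M and G1/S (0.0857 and 0.0717).

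**Figure D2:**
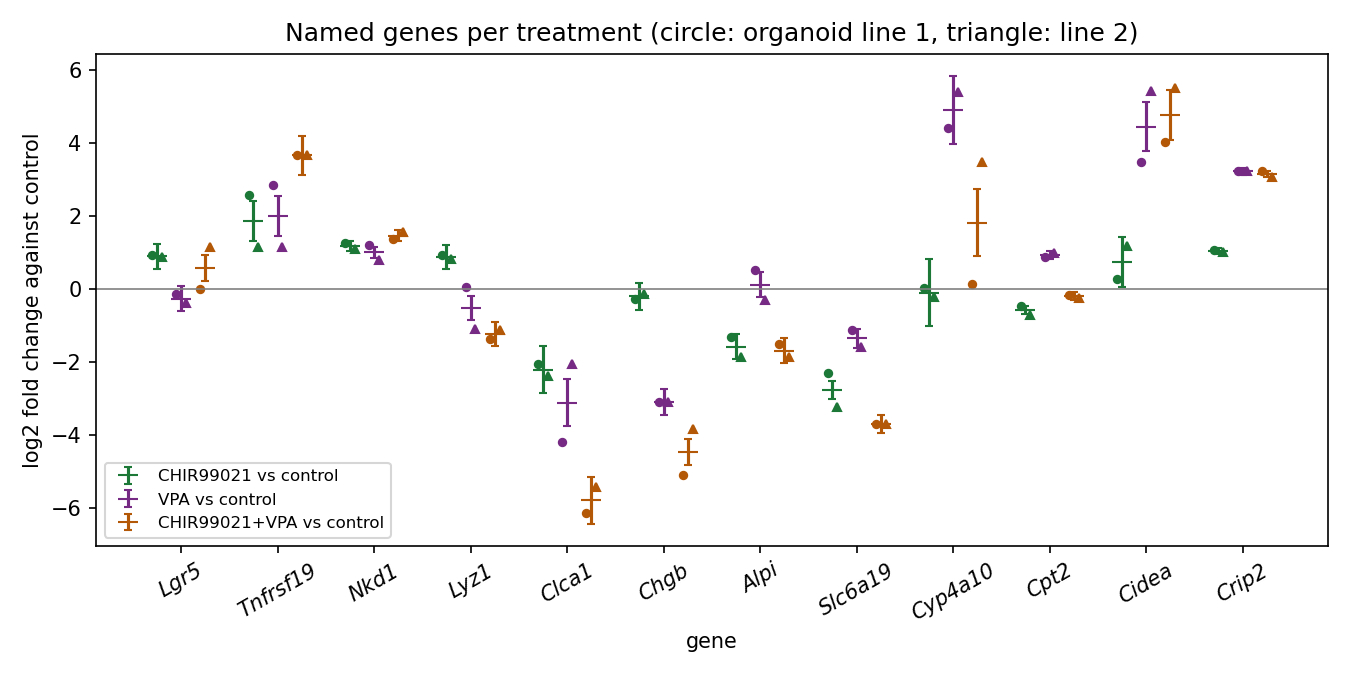
Log2 fold change against control (vertical axis) of 12 named genes (horizontal axis) for each treatment: dashes with bars give the fitted value ± SE, circles organoid line 1 and triangles line 2. Slc6a19 read -2.76 with CHIR99021 and -3.70 with both compounds, and Crip2 rose by 1.04 with CHIR99021, 3.22 with VPA and 3.14 with both.

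With VPA added to CHIR99021, secretory and cell cycle genes were lower and fatty acid oxidation genes higher as lists. With an estimated correlation the adjusted p was 0.226 to 0.483 for the secretory lists, 0.615 and 0.657 for G2/M and G1/S, and 0.588 for fatty acid oxidation. Chgb fell by 4.25 ± 0.36 (adjusted p = 0.00235), relative to CHIR99021 alone. So did Defa23 (-4.20 ± 0.40), Clca1 (-3.56 ± 0.64), Spdef (-2.25 ± 0.20) and Lyz1 (-2.11 ± 0.33, adjusted p = 0.0138). Of 22 Paneth cell genes, 12 fell and 1 rose (15 and 2 adjusted over the list alone; median -1.29), and of 25 goblet cell genes, 13 fell and 1 rose (14 and 1 adjusted over the list alone; median -0.88). Of 27 enteroendocrine genes, 6 fell (7 adjusted over the list alone), with Tph1 at -1.63 ± 0.25, and of 12 secretory progenitor genes, 4 fell (5 adjusted over the list alone), with Gfi1 at -1.36 ± 0.22. Of 31 G1/S genes, 8 fell (19 fell and 1 rose adjusted over the list alone; median -0.47), with Tk1 at -0.94 ± 0.12, and of 29 G2/M genes, 5 fell (15 adjusted over the list alone; median -0.41), with Ccnb1 at -0.58 ± 0.12. Of 11 fetal-like genes, 4 fell (5 adjusted over the list alone), among them Ly6d (-1.62 ± 0.17) and the secreted chaperone Clu (-2.06 ± 0.28). Of 32 fatty acid oxidation genes, 11 rose and 1 fell (15 and 1 adjusted over the list alone; median 0.48), with the carnitine carrier Slc25a20 at 1.18 ± 0.17 and Crot at 0.91 ± 0.11. Further rises were Reg3g (4.96 ± 0.38), Cidea (4.03 ± 0.68), the erythropoietin receptor Epor (3.10 ± 0.10) and Cubn (2.54 ± 0.21). The calls of Ccnb1 and Tph1 ended with the mean of their probes.

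Over all genes, 1194 rose and 734 fell, all in the same direction in both lines, as passing required. Rises made up 61.9% of the calls, 79.2% with median centring, 50.5% in the Cy5 channel alone and 52.0% in the authors' table of ratios. Camera gave adjusted p = 4.05e-10 for goblet cell, 1.64e-09 for G2/M, 1.96e-08 for G1/S, 2.82e-08 for Paneth cell, 5.16e-06 for fatty acid oxidation, 7.77e-06 for enteroendocrine, 2.16e-05 for secretory progenitor and 0.00662 for fetal-like genes. With an estimated correlation the adjusted p-values were 0.226, 0.615, 0.657, 0.396, 0.588, 0.483, 0.396 and 0.483. The count of 1928 was 3416 (1977 rose, 1439 fell) with the replicate block, 702 without control line 1 or line 2, 366 without CHIR99021 line 1, 287 without CHIR99021 line 2 and 787 without combination line 1. These ended 3, 8, 10 and 6 named calls in turn, Ccnb1 and Clca1 each time. The fetal-like call ended without CHIR99021 line 1 (median -0.62) and without combination line 2 (median 0.04). It also ended with outlier spots of all arrays kept in the background model (adjusted p = 0.209 by camera), which ended the calls of Crot and Ly6d as well. Agilent's own log ratios ended the calls of Ccnb1, Cidea and Cubn, and a fit of only the compared groups (289 genes) those of Ccnb1, Cidea, Crot and Tph1.

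With CHIR99021 added to VPA, enterocyte and fatty acid oxidation genes were lower as lists (adjusted p = 0.20 and 0.226 with an estimated correlation). Relative to VPA alone, the fatty acid binding proteins Fabp1 and Fabp2 fell by 4.01 ± 0.60 (adjusted p = 0.0396; -5.36 and -2.67 in the lines) and 3.71 ± 0.57. Adh4 (-4.45 ± 0.38), Slc6a19 (-2.35 ± 0.25) and the mucosal glycoprotein Dmbt1 (-4.61 ± 0.68) fell as well. All 32 fatty acid oxidation genes had negative values, and 10 fell (23 adjusted over the list alone; median -1.04), with Ppara at -1.37 ± 0.12 and Cpt2 at -1.13 ± 0.11. Of 47 enterocyte genes, 11 fell (28 adjusted over the list alone; median -1.01) and 1 rose (1 adjusted over the list alone), Cubn at 2.05 ± 0.21. Of 29 NRF2 and xenobiotic genes, 7 fell (14 fell and 3 rose adjusted over the list alone; median -0.56), with the glutathione transferases Gsta1 (-2.55 ± 0.30) and Gstm2 (-1.15 ± 0.11), whose families may cross-hybridise. Of 25 goblet cell genes, 3 fell (11 fell and 1 rose adjusted over the list alone; median -0.54), among them Tff3 (-1.24 ± 0.15) and the disulfide isomerase Agr2 (-1.51 ± 0.23). Of 22 Paneth cell genes, 4 fell (7 fell and 2 rose adjusted over the list alone), with Reg4 at -1.52 ± 0.24; the median was -1.15 in line 1 and -0.10 in line 2. Of 23 genes of the unfolded protein response, 1 fell (2 adjusted over the list alone), the chaperone Dnajb9 (-0.69 ± 0.10). The stem cell, Wnt, G1/S and G2/M lists had medians of 0.23, 0.11, 0.10 and 0.12, with 0 members passing by limma and 0 adjusted over the list alone in each; Lgr5 read 0.84 ± 0.35 (adjusted p = 0.350), with 0.14 and 1.54 in the lines. The largest rises after Cubn included the splicing factor Prpf19 (1.02 ± 0.13) and the interferon-inducible membrane protein Ifitm1 (0.78 ± 0.09).

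Over all genes, 17 rose and 198 fell, all in the same direction in both lines, as passing required. Rises made up 7.91% of the calls, and 25.2% in the Cy5 channel alone (567 genes). Camera gave adjusted p = 6.97e-23 for fatty acid oxidation, 1.76e-19 for enterocyte, 1.41e-08 for goblet cell, 1.24e-06 for NRF2, 0.000785 for stem cell, 0.00142 for Paneth cell, 0.0134 for G1/S, 0.0184 for unfolded protein response and 0.0405 for both G2/M and Wnt target genes. With an estimated correlation the adjusted p-values were 0.226, 0.20, 0.226, 0.396, 0.621, 0.588, 0.926, 0.665, 0.926 and 0.657. The count of 215 was 614 (115 rose, 499 fell) with the replicate block. It was 28 with outlier spots of all arrays kept in the background model, which ended 13 of the 16 named calls. A fit of only the groups compared gave 0 by limma (1448 with an unadjusted p under 0.05). Agilent's own log ratios gave 34 genes and ended 14 named calls, leaving Adh4 and Ppara. It was 7 without control line 1 or line 2, 77 without CHIR99021 line 1 or line 2, 41 without VPA line 2, 84 without combination line 1 and 137 without combination line 2, which ended 16, 7, 13, 10 and 4 named calls. Without VPA line 1, 171 genes passed and 10 named calls ended. Without VPA line 2 the G2/M and G1/S medians turned to -0.02 and -0.07 (adjusted p = 0.817 and 0.488) and the Wnt call ended (0.590). The Wnt call also ended without combination line 1 (median 0.10). By camera its adjusted p was 0.0532 with the replicate block, 0.0559 with outlier spots of all arrays kept and 0.0727 with Agilent's own log ratios. Without combination line 1 the Paneth cell call ended (0.184), without combination line 2 those of stem cell, G2/M, G1/S and unfolded protein response genes (0.101, 0.829, 0.0687 and 0.562, the last with a median of 0.04), and without VPA line 1 that of the unfolded protein response (0.209).

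The test of whether the combination departed from the sum of the single effects on the log2 scale passed for 0 genes by limma. Fewer genes had an unadjusted p under 0.05 than that threshold would give with no effect. The smallest adjusted p was 0.251, and 511 genes had an unadjusted p under 0.05; the replicate block gave 0 genes as well (816 with an unadjusted p under 0.05), and leaving out VPA line 2 gave 1. Fabp1 read -2.11 ± 0.85 (-4.05 and -0.16 in the lines) and Lyz1 read -1.59 ± 0.47, with an adjusted p of 1 for both. As lists, 7 had values below the sum of the single effects by camera, with 0 members passing over all genes by limma. They were fatty acid oxidation (median -0.44, adjusted p = 1.72e-12, 0 adjusted over the list alone), Paneth cell (-0.39, 3.63e-08, 6 adjusted over the list alone), fetal-like (-0.93, 3.15e-07, 3 adjusted over the list alone), G2/M (-0.15, 0.000505, 0 adjusted over the list alone), NRF2 (-0.15, 0.00136, 5 adjusted over the list alone), secretory progenitor (-0.17, 0.00327, 0 adjusted over the list alone) and G1/S genes (-0.12, 0.0145, 0 adjusted over the list alone). Their adjusted p-values with an estimated correlation were 0.396, 0.396, 0.226, 0.864, 0.588, 0.573 and 0.926. Fry called none of these lists in the interaction. With the replicate block the tuft cell list also passed by camera (adjusted p = 0.0103), with a median of the other sign (0.27). Without VPA line 1 the G1/S median turned to 0.08 (adjusted p = 0.124), the G2/M median to 0.0043 and the secretory progenitor call ended (0.138). The G2/M call also ended without CHIR99021 line 1 (0.115) and combination line 1 (0.226). The call of G1/S genes ended without combination line 1 (0.0828) and line 2 (0.0688), that of secretory progenitor genes without combination line 1 (0.0574), and that of NRF2 genes without CHIR99021 line 1 (median 0.02, adjusted p = 0.0868) and combination line 2 (median 0.08, adjusted p = 0.199).

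The responses to the single compounds overlapped in part. Of the genes that rose with CHIR99021, 15 of 22 also rose with VPA (1.44 expected of independent lists), Nkd1 and Crip2 among them, and 47 of the 194 that fell, Treh among them, also fell with VPA (8.29 expected). Across genes the 2 sets of fold changes correlated with r = 0.161, where unchanged groups measured against the same control arrays gave 0.50; the covariance was 0.0225 against a simulated 0.0185. This simulation and those below drew arrays independently and so left out the organoid line. They also gave all groups the same spread for a gene, although control ratios varied less. The median SD between lines was 0.054 for control, 0.0945 with CHIR99021 and 0.125 with VPA. The simulated values are thus no close baseline. Within lines 1 and 2 the observed r was 0.352 and 0.0594. Between arrays that share no control, r was 0.0177 for CHIR99021 in line 1 with VPA in line 2 and 0.0864 the other way round. Of the genes that rose with VPA, 927 also rose with the combination (106 expected of independent lists), and 576 of those that fell also fell (58.4 expected). Of the 22 and 194 genes that rose and fell with CHIR99021, 16 and 166 did so with the combination (1.85 and 13.8 expected). In 100 simulations with as many effects placed on random genes and the control arrays shared, the overlaps averaged 2.93 and 6.95 for CHIR99021 with VPA, 80.9 and 45.7 for VPA with the combination, and 3.15 and 11.5 for CHIR99021 with the combination. The same simulated lists would share 0.927, 4.77, 67.4, 34.7, 1.19 and 8.96 if independent. Part of the excess may thus come from the shared control arrays, which are too few to be split into separate sets.

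Another 12 of the 28 lists passed in no comparison by camera. Markers of cell types foreign to an epithelial culture were among them, with lowest adjusted p-values of 0.291 for mesenchymal, 0.620 for leukocyte and 0.845 for endothelial genes. The lowest adjusted p was 0.0672 for interferon response, 0.252 for cyclin-dependent kinase inhibitors and p53 targets, 0.301 for M cell, 0.373 for MHC class II, 0.398 for cholesterol synthesis, 0.505 for replication-independent histone, 0.678 for Notch pathway, 0.725 for neuronal and 0.784 for histone deacetylase genes. Cholesterol synthesis genes passed in at least 1 comparison when any 1 of the 6 treated arrays was left out, with medians of either sign: with CHIR99021 the median was -0.31 without CHIR99021 line 1 (adjusted p = 0.0101) and 0.36 without line 2 (adjusted p = 0.000709). Interferon response genes passed for the combination against CHIR99021 with no filter (adjusted p = 0.0273), without CHIR99021 line 2 (0.0281) and without combination line 2 (0.0105), which also let them pass in the interaction (0.0199). Median, mean and test had the same sign in all 55 called pairs of list and comparison, and differed in sign in 32 of the 113 others. No list call held with an estimated correlation between members (0 of 168), and fry, which tests whether a list's genes move one way, called 17, of which 14 were among the 55. The 14 included goblet cell genes in every comparison but the interaction. Enterocyte genes passed with CHIR99021, with the combination and in the combination against VPA. Fatty acid oxidation genes passed with VPA and in the combination against VPA, and Paneth cell genes with the combination and against CHIR99021. The rest were secretory progenitor genes in the combination against CHIR99021 and NRF2 genes against VPA. The other 3 were mesenchymal genes in the combination against CHIR99021 (adjusted p = 0.0445, median 0.07) and neuronal genes in the combination against control and against CHIR99021 (adjusted p = 0.0445 and 0.0242). The neuronal test was upward while the medians were -0.02 and -0.06.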

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

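The tests on the shift of fatty acid oxidation and enterocyte genes and on the low count for CHIR99021 were chosen after the results were seen, the one on pooled variance after its own value was known. Groups of 2 arrays are too small for a test of single outlying arrays.

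The effect of CHIR99021 differed with and without VPA for 7 gene lists by camera's test of the interaction with a preset correlation, each below the sum of the single effects. None passed with an estimated correlation or by fry, and limma called 0 genes. The medians were -0.442 for fatty acid oxidation, -0.386 for Paneth cell, -0.927 for fetal-like, -0.173 for secretory progenitor, -0.148 for NRF2, -0.153 for G2/M and -0.116 for G1/S genes. The G2/M and G1/S lists had medians of opposite sign in the 2 lines, a difference that was not tested: -0.480 in line 1 and 0.129 in line 2 for G2/M, and -0.332 and 0.125 for G1/S. The same lists also split in the combination against VPA, again untested, with an overall median of 0.123 (-0.105 and 0.326 in lines 1 and 2) for G2/M and 0.104 (-0.037 and 0.296) for G1/S genes.

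The fatty acid oxidation list was higher with VPA and lower when CHIR99021 was added, by camera with a preset correlation (adjusted p = 0.396 and 0.226 with an estimated correlation). Whether a higher share of absorptive enterocytes with VPA may account for the rise stays open: the enterocyte median was -0.179 against 0.908 for fatty acid genes, a gap just over the SD of 1.01 among enterocyte members, and the medians were -0.065 and 0.804 in line 1, a gap under that SD, and -0.058 and 1.101 in line 2, a gap over it. When CHIR99021 was added to VPA, both lists were lower by nearly the same amount (difference of medians -0.0271). A lower share of enterocytes may account for that part as a hypothesis, although Cubn, an enterocyte gene, rose there. The enterocyte median was -1.01 there and -1.0 with CHIR99021 alone, where that of fatty acid genes was only -0.391. Falls of enterocyte genes of about the same size thus went with unequal falls of fatty acid genes. Action of VPA as a fatty acid on PPAR signalling, or through histone deacetylases, was not tested and stays open.

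CHIR99021 called 216 genes against 2089 with VPA, in a model that pools 1 variance per gene over all 4 groups. With only the compared groups fitted the counts were 1086 and 1575. That the pooled variance accounts for much of the gap is a hypothesis which these counts prompted and so cannot test. Without background correction, which does not use the local background, the counts were 231 and 2239. This cannot decide whether the speck on 1 CHIR99021 array adds to the gap, since its marked spots were left out of both fits. In the main fit, pooling gave both comparisons the same SE for each gene (median 0.126), so fewer calls for CHIR99021 there reflect smaller fold changes. The SD of the fold changes across genes was 0.31 with CHIR99021 and 0.44 with VPA. Doses of different compounds cannot be set against each other, so which compound is the stronger stays open.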

How the results depend on the processing

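The results rest on a normexp fit without spots marked as outliers, which was chosen after the data were examined and after the usual fit on all spots had called 0 genes for CHIR99021. That fit stands below as an alternative; the other alternatives were planned, and all planned ones were run. For each change below the cause was not tested, except that leaving out an array or fitting fewer groups leaves fewer residual degrees of freedom, a minimum fold change can only remove calls, and ratios against 0 keep the dye bias of the control arrays. Where a control array leaves the fit, the smaller control spread leaves the pooled variance as well.

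Counts are given for CHIR99021, VPA and the combination against control, then the combination against CHIR99021 and against VPA, where they moved by over 1.5 times from 216, 2089, 2987, 1928 and 215. With the replicate block they were 557, 3752, 4822, 3416 and 614, and the block gained Krt20, Alpi, Chga and Lyz1. Over the 168 list tests it gained 7 calls: stem cell with the combination, glycolysis with CHIR99021, with VPA and in the combination against VPA, and tuft cell in the combination against CHIR99021, against VPA and in the interaction. It ended 2 (G2/M with the combination, Wnt in the combination against VPA) and changed no other call of a list or named gene. A minimum log2 fold change of 1 gave 111, 551, 888, 497 and 142. Outlier spots kept gave 0 for CHIR99021 and 28 for the combination against VPA, and moved the technical SD from 0.065 to 0.073. Agilent's log ratio gave 36 and 34 for the same contrasts. For CHIR99021, offset 16 gave 143, trend and robust options 85 and scale normalisation 392. The compared groups alone gave 1086 for CHIR99021, 289 for the combination against CHIR99021 and 0 against VPA. Ratios against 0 gave 4321, 7034 and 7805. The Cy5 channel with the block gave 3499, 5241, 3871 and 567 for the last 4 contrasts. Median centring gave 1130 for VPA and 1156 for the combination against CHIR99021.

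Leaving out each array gave 1 to 271 genes for CHIR99021, 120 to 2484 for VPA, 542 to 3250 for the combination, 287 to 2054 and 7 to 171 for the combination against CHIR99021 and VPA, and 0 to 1 for the interaction. Of 55 list calls, 0 held with an estimated correlation and 14 with fry, which called 17 of the 168 pairs.

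Among the 137 gene values and 59 list results run under each setting, direction reversed in 12 cases, none called under the setting. Among the other lists, cholesterol synthesis passed with a turned median in the combination against VPA (-0.35 without VPA replicate 2), with CHIR99021 (-0.31 without CHIR99021 replicate 1) and in the interaction (0.41, 0.37 and 0.34 without CHIR99021 replicate 1, VPA replicate 1 and combination replicate 2). So did unfolded protein response with the combination (-0.15 without combination replicate 1) and glycolysis in the interaction (0.48 without combination replicate 2). Lgr5 with VPA ranged from -0.64 (without VPA replicate 1) to 0.12 (reversed, without VPA replicate 2) over arrays left out. The test of the stem cell list with VPA turned down with fry (median 0.075), ratios against 0 (0.076), without VPA replicate 1 (0.022) and without control replicate 2 (0.064); over arrays left out its median ranged from 0.022 to 0.11. That of fatty acid oxidation with the combination turned down with fry (0.020), ratios against 0 (-0.026) and without combination replicate 2 (0.017); over arrays left out its median ranged from -0.058 to 0.061. Without VPA replicate 2, G2/M read -0.015 and G1/S -0.070 in the combination against VPA; without VPA replicate 1 they read 0.0043 and 0.083 in the interaction. Over arrays left out, G2/M ranged from -0.015 to 0.28 and G1/S from -0.070 to 0.28 in the former, and from -0.30 to 0.0043 and from -0.29 to 0.083 in the latter. Over the settings run for them, 2694 gene values kept direction and side of the threshold, 516 lost and 36 gained the call. For lists these were 702, 138 and 9. Signal limits the genes: only those well above background were tested.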

Other observations

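The test on the glycolysis list was set out before its own value was seen, after the list's split between the lines had been noticed.

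The glycolysis list was called by camera with the combination (adjusted p = 0.0196, and 0.926 with an estimated correlation) but not with CHIR99021 (0.0712) or VPA (0.16). With the replicate block it passed for both single compounds (0.00219 and 0.0137). For CHIR99021 it also passed with no filter (0.0327), and for both in some fits with 1 array left out. The list's values differed between the lines. The medians of the 20 genes' own log2 ratios were 0.87, 0.84 and 1.38 in line 1 with CHIR99021, VPA and both, and 0.077, 0.050 and 0.22 in line 2; the control arrays read 0.032 and -0.0066. An unusual control array in line 1 as the subtracted baseline is argued against, since the lowest treated median before any subtraction was 0.842. This does not cover the control RNA itself, which the treated arrays of line 1 shared in Cy3. Control RNA low in these genes would give the same values, so that stays open. A difference between the lines or their cultures, such as density or oxygen supply, or between slides may account for the split. Line and slide coincide, so these cannot be told apart, and neither was tested.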
